A study of Bos taurus with 92 samples.

How the data were processed

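Gene expression had been measured in single bovine blastocysts and in donor cells on a custom 2-colour cDNA microarray. The embryos came from nuclear transfer (NT, an oocyte given the nucleus of a somatic donor cell), artificial insemination (AI) or fertilisation in vitro (IVF). Each sample was hybridised against the same reference RNA on 2 arrays, once with the sample in Cy5 and once with the sample in Cy3. The 92 arrays held 14 AI, 15 IVF and 15 NT embryos and 2 donor cell samples. Per the labels, RNA was amplified linearly, with more rounds for embryos and donor cells than for the reference, and aminoallyl cDNA was coupled to the dyes. The deposited values are log2 ratios of the dye channels per spot, and the authors' labels name no scanner software, background correction, normalisation or direction of the ratio. No intensities were held, so that background, spot quality and intensity-dependent dye bias could not be examined, and control spots could not be told from others.

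The table held 16416 spots. Adjacent spots carried the same annotation in all 5693 annotated pairs and were treated as the 2 spots of a probe, which gave 8208 probes. Duplicate spots correlated with a median r of 0.793 over the arrays, from 0.720 to 0.914. A fill value of 16.61, the log2 of a ratio of 1e+05, stood in 2657 cells and was set to missing, and 4.39% of the cells were empty. Missing values averaged 5.37% in AI, 4.18% in IVF, 4.60% in NT and 1.51% in donor cell samples. The other values ran from -9.82 to 8.26. The 2 arrays of a sample correlated with r from -0.743 to -0.301 as deposited, so that the values were read as dye ratios, and arrays with the sample in Cy3 were turned in sign. After turning, r of the 2 arrays was 0.577 to 0.763 in AI, 0.584 to 0.796 in IVF, 0.651 to 0.730 in NT and 0.301 to 0.395 in donor cells. That the ratio is Cy5 over Cy3 was inferred and is likely rather than certain. Under this reading 15 to 19 of 30 fibroblast and matrix genes were higher in donor cells and 1 to 3 in embryos, and 15 to 19 of 31 trophectoderm genes were higher in embryos and 2 in donor cells. The number of arrays limits the precision.

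The plan written before the data were examined listed centring of each array on its median, quantile normalisation and scaling to a common median absolute deviation as alternatives, which left the deposited scaling as the implied choice. Array medians then ran from -2.14 to 0.862, which showed that the deposited ratios were not centred. Each array was therefore centred on its median in all values given here unless the text says "as deposited". This choice was made after the array medians were seen and before any test between groups was run, and the uncentred values became an alternative chosen after seeing the data. Directions are thus relative to the median probe of the array.

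Duplicate spots were averaged, then the 2 arrays of a sample, so that each embryo or donor cell sample counted as 1 replicate. A probe was tested when at least 50% of the samples of each kind of embryo and both donor cell samples had a value, which left 7992 probes and removed 216. Gene names came from the probe table, in which 5598 probes had 1 symbol, 95 had several and 2515 had none. Of the probes with 1 symbol, 5591 matched the reference gene table by Entrez ID, 7 did not, and no symbol changed. Values of probes with the same single symbol were averaged into 4398 genes.

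All 46 samples entered a single linear model of group means with limma 3.58.1 in R 4.3.3, with moderated variances from eBayes and 2-sided tests. P values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Differences are log2 values of the first group minus the second, with the standard error (SE) of the model. The counts of probes come from the fit to probes and all named genes from the fit to genes. The genes named for each comparison were fixed by rule before the data were examined. They are the 10 largest rises and the 10 largest falls among genes past the threshold, up to 4 members of smallest p from each gene list and 11 genes chosen beforehand. The text does not give all of them: of the largest changes against donor cells only some are given, and 1 of the largest falls in NT against IVF embryos is left out for reasons unrelated to its values. Of these 11, POU5F1, NANOG, CDX2, DNMT1 and IFNT were not measured.

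Before the data were examined, 23 gene lists were fixed for cell types, pathways and complexes. Of these, 18 had at least 5 measured members and were tested with limma camera at a preset correlation between genes of 0.01, with missing values filled by the group mean. Camera was repeated with an estimated correlation, and fry was run beside it. The list of histones was defined by symbol pattern and took in H19, which is not a histone gene, so that it was also run without H19. Other patterns likewise took in genes that are no subunits or factors, among them the chaperones PSMG1 and PSMG4, the activators PSME1 and PSME4, the inhibitor PSMF1 and PSME3IP1 for the proteasome. Further examples are the kinases EIF2AK1, EIF2AK4 and EEF2K for translation factors and the assembly factors NDUFAF3 and NDUFAF5 for oxidative phosphorylation. The list of ribosomal proteins took in RPL7L1, a paralogue of RPL7. A further test, added after the camera results had been seen, took the mean of each list in each embryo relative to all genes. For this, each gene was first set relative to its mean over all embryos, and the mean of all genes of the embryo was subtracted. The kinds of embryo were compared by a 2-sided permutation test with 1e+05 resamples, adjusted over 54 tests. The smallest p that this test can give is 1e-05, or 7.7e-05 after adjustment.

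Pearson r across probes was computed between each embryo and the mean of the donor cells, and between each embryo and the mean of the other embryos of its kind. Each embryo gave 1 value, and the kinds of embryo were compared by 2-sided permutation tests adjusted over the 3 pairs. The slope of the NT minus IVF difference on the donor cell minus AI difference, which share no samples, was tested with 10000 permutations of the embryo labels. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

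Alternatives fixed before the data were examined were other array scalings, filters on missing values, single dye orientations, arrays kept apart with dye as a covariate, array weights, a robust variance prior, stricter thresholds, gene-level values, subsets of embryos by label, each sample left out, and other list tests. Alternatives chosen after seeing the data were the arrays as deposited, IVF embryo 11 left out, histones without H19 and the test of list means per embryo. The procedure was tested on simulated data in which 200 probes were changed. In comparisons of kinds of embryo 40.3% to 43.3% of probes changed by 0.5, 73.1% to 85.1% of those changed by 1 and 100% of those changed by 2 on the log2 scale were found. In the comparison of NT embryos with donor cells the shares were 2.99%, 17.9% and 83.3%. False calls were 2.82% to 6.49% of all calls. Of 18 simulated gene lists, the 3 shifted by -0.4 were called by camera and 0 others were. The simulated noise was independent between probes and between genes. The false calls that camera makes when genes vary together were therefore not tested by it.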

Results

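Transcript levels relative to a common reference were available for 44 single bovine blastocysts and for 2 samples of the donor cells used for nuclear transfer. The embryos were 14 from artificial insemination (AI), 15 fertilised in vitro (IVF) and 15 from nuclear transfer (NT). The labels of 3 AI embryos begin with H, and those of 8 NT embryos begin with 2_ and of 7 with 3_, without further explanation. No hybridisation batch or date is given, so that batch and kind of embryo cannot be told apart. The array tested 7992 probes and 4398 named genes. The series title names nuclear reprogramming as its subject, and the 3 kinds of embryo were compared with each other and with the donor cells. Values after ± are standard errors unless stated otherwise.

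Ribosomal protein transcripts were lower in NT than in AI embryos, and PSPH, the phosphatase of the last step of serine synthesis, was higher. PSPH rose by 2.47 ± 0.34 on the log2 scale (15 NT against 14 AI embryos, adjusted p = 4.44e-06) and exceeded the AI mean in 15 of 15 NT embryos. CASP6, an executioner caspase, had the smallest adjusted p among the largest falls, with a difference of -1.17 ± 0.13 (adjusted p = 2.64e-08, below the AI mean in 15 of 15 NT embryos). TFAP2A, a transcription factor of the trophectoderm, fell by 1.42 ± 0.23 (adjusted p = 3.44e-05, 15 of 15 NT embryos). In all, 598 of 7992 probes differed between NT and AI embryos, of which 265 were higher and 333 lower in NT embryos, and 68 differed by at least 2-fold. At the level of genes 355 of 4398 differed.

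The other large rises in NT over AI embryos were in OCIAD2 (1.99 ± 0.43), MFSD6 (1.47 ± 0.24), MAN1A2, a Golgi mannosidase of N-glycan trimming (1.44 ± 0.35), HRH1, a histamine receptor (1.42 ± 0.32), and MTERF2, a mitochondrial transcription factor (1.37 ± 0.30). POLR1H, a subunit of RNA polymerase I, rose by 1.22 ± 0.30, PLPP1, a lipid phosphate phosphatase, by 1.17 ± 0.18, KCNK1, a potassium channel, by 1.11 ± 0.28 and ATF4, a transcription factor of the amino acid response, by 1.11 ± 0.17. Adjusted p of these 9 genes lay between 1.14e-05 and 0.00725, and each exceeded the AI mean in 13 to 15 NT embryos. The other large falls were in the chemokine CCL26 (-1.60 ± 0.28), the homeobox gene MEIS2 (-1.59 ± 0.23), the unconventional myosin MYO1D (-1.56 ± 0.38) and the lysosomal thiol reductase IFI30 (-1.50 ± 0.30). SSLP1 (-1.40 ± 0.36), the tetraspanin CD81 (-1.40 ± 0.21), SNAPC2, a subunit of the snRNA-activating complex (-1.36 ± 0.35), and SCAND1 (-1.30 ± 0.28) also fell. Adjusted p of these 8 genes lay between 6.93e-06 and 0.0112, and each lay below the AI mean in 13 to 15 of 15 NT embryos, or in 12 of the 12 with a value for SNAPC2. All 20 of the largest changes kept their call with arrays as deposited and with either dye orientation alone.

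**Figure D1:**
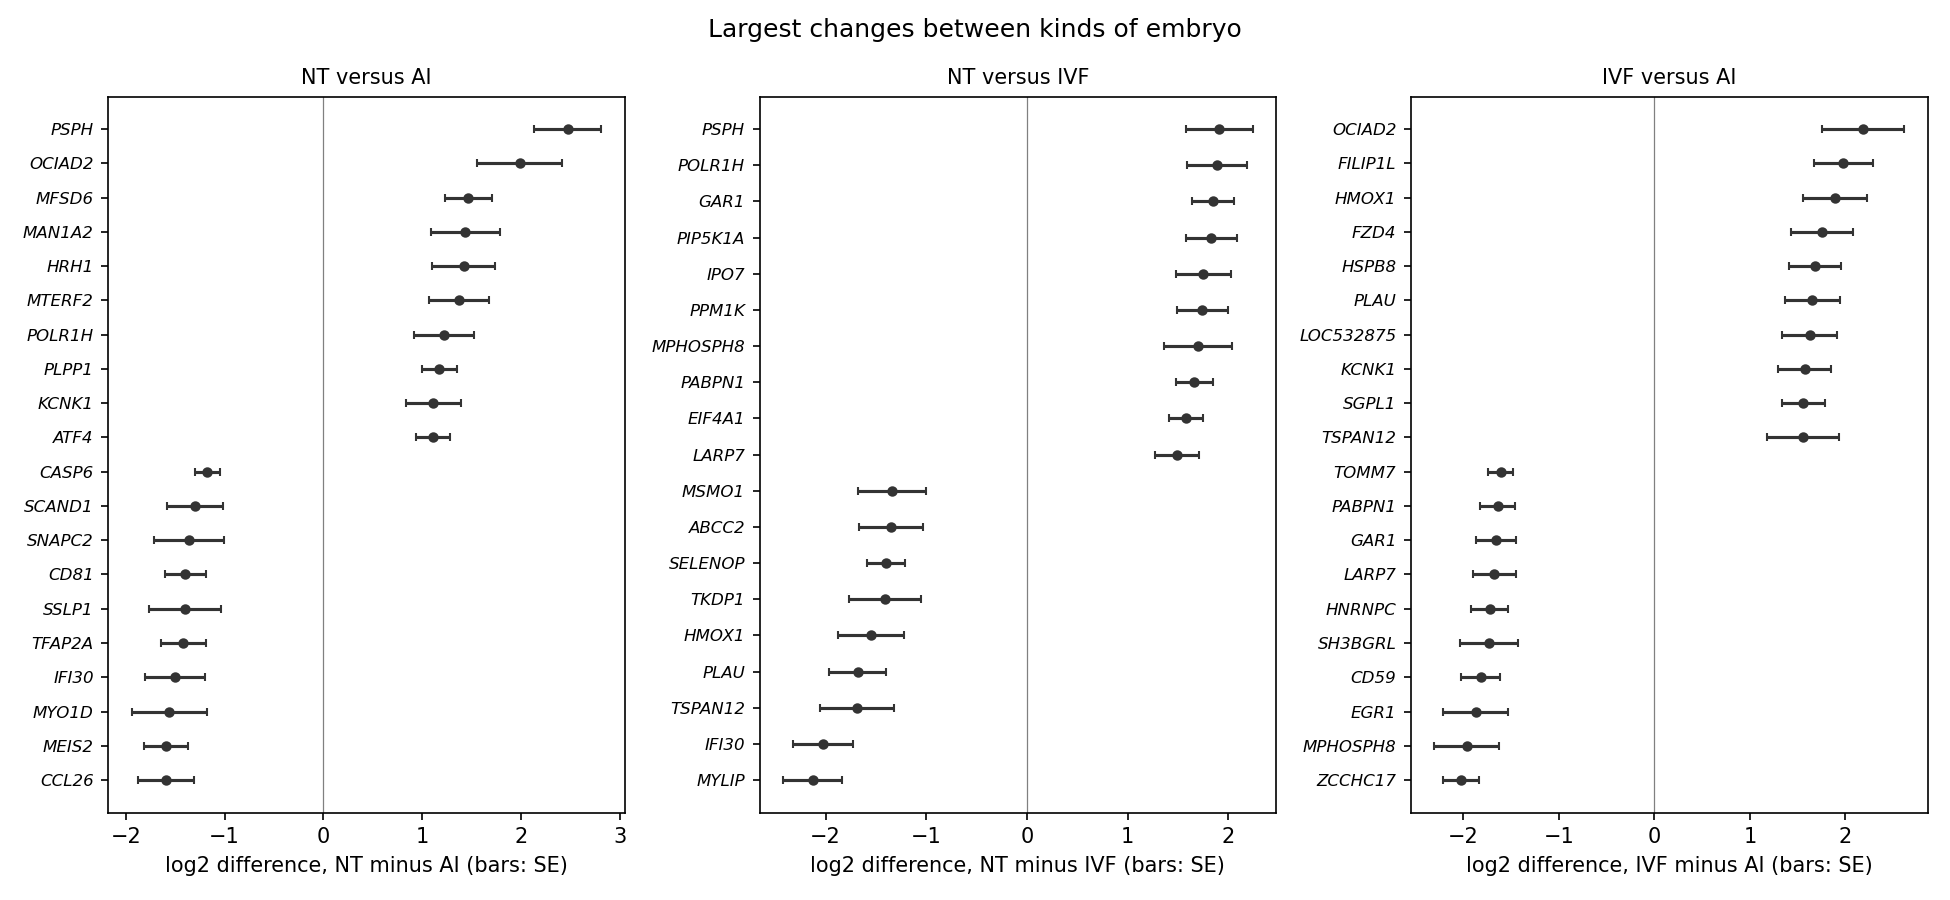
Largest rises and falls between kinds of embryo among genes past the threshold, as log2 difference (x axis) per gene (y axis), with bars for the SE (14 AI, 15 IVF and 15 NT embryos), with 1 fall in NT against IVF not shown. PSPH was highest in NT over AI (2.47) and NT over IVF (1.91), and OCIAD2 was highest in IVF over AI (2.18).

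Of 45 ribosomal protein genes, 24 fell and 0 rose in NT against AI embryos (32 fell when adjusted over the list alone), with a median of -0.40 that became 0.016 with arrays as deposited, where 2 rose and 2 fell. Camera placed the list below the other genes (adjusted p = 7.21e-24), and the call held at adjusted p = 0.0168 with an estimated correlation. The list mean per embryo, relative to all genes, was lower by -0.41 in NT embryos (permutation adjusted p = 7.7e-05), below the AI mean in 15 of 15. Examples are RPLP1 (-0.90 ± 0.11, adjusted p = 6.95e-07, 15 of 15 NT embryos) and RPL35A (-0.95 ± 0.14, adjusted p = 7.83e-06, 15 of 15). RPS10 (-0.55 ± 0.09) and RPS7 (-0.63 ± 0.11) fell too, and their calls ended with arrays as deposited and with the sample in Cy3 alone.

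Of 53 genes of oxidative phosphorylation, 3 fell (3 when adjusted over the list alone), NDUFA8 (-0.49 ± 0.11), NDUFC2 (-0.60 ± 0.14) and NDUFS5 (-0.50 ± 0.13), all subunits of complex I, and 0 rose, with a median of -0.11 that turned to 0.32 as deposited, where all 3 lost their call and 15 other members rose. The call of this list (adjusted p = 0.00908) was lost at adjusted p = 0.466 with an estimated correlation and also as deposited, and the mean per embryo was lower by -0.13 (permutation adjusted p = 0.022, 13 of 15 NT embryos). Of 31 trophectoderm genes, 4 fell and 0 rose (6 fell when adjusted over the list alone), with a median of -0.13 that turned to 0.28 as deposited, where 8 rose and 2 fell. They were TFAP2A, SSLP1 and the pregnancy-associated glycoproteins PAG8 (-0.39 ± 0.11) and PAG11 (-0.62 ± 0.20). PAG8 and PAG11 lost their call with the sample in Cy5 alone, with 1 probe per gene and as deposited. PAG11 lost it also with quantile normalisation and with scaling to a common median absolute deviation. The call of the trophectoderm list (adjusted p = 0.0276) was lost with quantile normalisation and at adjusted p = 0.466 with an estimated correlation, and its mean per embryo was lower by -0.26 (permutation adjusted p = 0.0013, 14 of 15 NT embryos).

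Among the lists that camera did not call, 4 of 16 genes of glycolysis and glucose transport fell and 0 rose (adjusted p = 0.125), with a median of -0.017 that turned to 0.42 as deposited, where 5 rose and 0 fell. These were the glycolytic enzymes TPI1 (-0.63 ± 0.12), PGAM1 (-0.60 ± 0.12), ENO1 (-0.62 ± 0.18) and ALDOA (-0.56 ± 0.14), and none kept its call as deposited. ENO1 lost its call also with the sample in Cy3 alone, and ALDOA with 1 probe per gene. The mean of this list per embryo was lower by -0.16 in NT embryos (permutation adjusted p = 0.0054, 15 of 15). Of 28 antioxidant genes, 4 rose and 5 fell (adjusted p = 0.874), with SOD1 at 0.60 ± 0.17, PRDX2 at -0.51 ± 0.11, SOD2 at -0.50 ± 0.13 and GPX4 at -0.37 ± 0.11. Of 26 DNA methylation and chromatin modifiers, the architectural factor CTCF (0.77 ± 0.14) and the remodeller CHD4 (0.67 ± 0.12) rose and 0 fell (adjusted p = 0.856). Of 32 heat shock and folding genes, HSF1 (-0.48 ± 0.11) and CCT3 (-0.40 ± 0.11) fell (adjusted p = 0.704). As deposited 12 antioxidant genes, 12 chromatin modifiers and 13 heat shock genes rose and 0 fell. PRDX2, SOD2, GPX4, HSF1 and CCT3 lost their call as deposited and with the sample in Cy3 alone.

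Of 14 imprinted genes, H19 rose (0.54 ± 0.13) and CD81 fell (adjusted p = 0.704). Of 34 translation factors, 3 rose and 2 fell (adjusted p = 0.874), with EIF4B at 0.64 ± 0.13 and EEF1B2 at -0.47 ± 0.14. Of 27 proteasome genes, 3 rose and 1 fell (adjusted p = 0.946), with the assembly chaperone PSMG1 at 0.48 ± 0.12 and PSMA7 at -0.37 ± 0.10. Of 10 cholesterol and lipid synthesis genes, EBP (-0.67 ± 0.20) and ACSL1 (-0.69 ± 0.21) fell (adjusted p = 0.0659). The list median of cholesterol synthesis was -0.15, and 0.27 as deposited. The mean of that list per embryo, relative to all genes, was lower by -0.36 (permutation adjusted p = 0.044, 15 of 15) and that of the apoptosis list by -0.14 (permutation adjusted p = 0.0096, 14 of 15). As deposited 19 translation factors and 11 proteasome genes rose and 0 fell, and 8 imprinted genes rose and 1 fell. H19 lost its call with the sample in Cy3 alone, EIF4B with the sample in Cy5 alone, and EEF1B2, PSMA7, EBP and ACSL1 with the sample in Cy3 alone and as deposited. Of 9 apoptosis genes CASP6 alone fell and 0 rose (adjusted p = 0.704), against 1 and 4 as deposited. Of the genes chosen beforehand none passed, with KRT18 at -0.34 ± 0.16, DNMT3A at -0.53 ± 0.23, HDAC1 at -0.057 ± 0.088, IGF2R at -0.22 ± 0.12, COL1A2 at -0.0026 ± 0.11 and VIM at 0.013 ± 0.089.

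With arrays as deposited the median probe lay 0.44 higher in NT than in AI embryos, and 3194 probes differed, of which 3161 were higher and 33 lower in NT embryos, against 265 and 333 after centring. As deposited 298 of the 598 probes and 36 of the 59 named genes past the threshold kept their call, and PAG8, CCT3, GPX4, EIF3CL and PSMA7 turned in direction. The 8 NT embryos labelled 2_ alone gave 321 probes and the 7 labelled 3_ gave 294. Arrays with the sample in Cy5 alone gave 1016 probes, and 470 of the 598 kept their call. Arrays with the sample in Cy3 alone gave 319, and only 220 of the 598 probes and 39 of the 59 named genes kept their call.

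NT embryos had higher transcripts of oxidative phosphorylation and of histones than IVF embryos, and 6 of 10 genes of cholesterol and lipid synthesis were lower, a list call lost at adjusted p = 0.0743 with an estimated correlation. MYLIP, a ubiquitin ligase that acts on the low-density lipoprotein receptor, fell by 2.13 ± 0.29 (15 NT against 15 IVF embryos, adjusted p = 4.77e-07) and lay below the IVF mean in 15 of 15 NT embryos. GAR1, a protein of ribonucleoproteins that guide RNA pseudouridylation, rose by 1.85 ± 0.21 (adjusted p = 7.07e-09, 15 of 15), and PSPH rose by 1.91 ± 0.33 (adjusted p = 2.62e-05, 14 of 15). In all, 1835 probes differed, of which 959 were higher and 876 lower in NT embryos, and 206 differed by at least 2-fold. At the level of genes 1066 differed.

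The other large rises included POLR1H at 1.89 ± 0.30, the nuclear poly(A)-binding protein PABPN1 at 1.66 ± 0.18, the RNA helicase EIF4A1 at 1.58 ± 0.17 and the La-related protein LARP7 at 1.49 ± 0.22. The kinase PIP5K1A (1.83 ± 0.25), the importin IPO7 (1.75 ± 0.27), the mitochondrial phosphatase PPM1K (1.74 ± 0.25) and the heterochromatin protein MPHOSPH8 (1.70 ± 0.34) rose as well. Adjusted p of these 8 genes lay between 2.71e-09 and 0.000196, and each exceeded the IVF mean in 14 or 15 NT embryos. Other large falls were in IFI30 (-2.03 ± 0.30), the tetraspanin TSPAN12 (-1.69 ± 0.37), the urokinase PLAU (-1.68 ± 0.28) and the haem oxygenase HMOX1 (2.92-fold). The trophoblast protein TKDP1 (-1.41 ± 0.36), selenoprotein P, SELENOP (-1.40 ± 0.19), the exporter ABCC2 (-1.35 ± 0.32) and the sterol oxidase MSMO1 (-1.34 ± 0.34) fell too. Adjusted p of these 8 genes lay between 2.39e-07 and 0.00294, each below the IVF mean in 14 or 15 NT embryos, and all 20 of the largest changes kept their call as deposited and with either dye orientation alone.

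Of 53 genes of oxidative phosphorylation, 29 rose and 2 fell in NT against IVF embryos (33 and 2 when adjusted over the list alone), with a median of 0.42, against 40 and 0 as deposited. Camera called the list (adjusted p = 4.49e-09), and the call held at adjusted p = 0.015 with an estimated correlation. The mean per embryo was higher by 0.36 in NT embryos (permutation adjusted p = 7.7e-05), above the IVF mean in 15 of 15. NDUFA2 (1.10 ± 0.11), COX7A2 (1.05 ± 0.11), NDUFB9 (1.06 ± 0.14) and UQCRQ (0.92 ± 0.13) are subunits of complexes I, III and IV, with adjusted p from 6.23e-10 to 1.49e-06 and 15 of 15 NT embryos above the IVF mean. Of the 10 genes in the histone list, 5 rose and 0 fell (7 rose when adjusted over the list alone; median 0.36, adjusted p = 0.000277, and adjusted p = 0.00592 with an estimated correlation). H2AZ1 rose by 1.01 ± 0.09 (adjusted p = 1.05e-10, 15 of 15), H3-3A by 0.98 ± 0.15, H2AZ2 by 0.71 ± 0.11 and H2AJ by 0.34 ± 0.10. Without H19, which is no histone gene and did not pass (0.29 ± 0.12), 5 of 9 rose (unadjusted p = 4.3e-05). As deposited 8 histone genes rose and 0 fell. The mean of the histone list per embryo was higher by 0.45 (permutation adjusted p = 7.7e-05, 15 of 15). In NT against AI embryos H19 alone of this list rose and 0 fell (median -0.017, camera adjusted p = 0.946), against 6 and 0 as deposited. There the mean per embryo differed by -0.047 (permutation adjusted p = 0.67).

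Of 10 cholesterol and lipid synthesis genes, 6 fell and 0 rose (6 when adjusted over the list alone), with a median of -0.59. As deposited 3 fell and 1 rose, with a median of -0.23. The call (adjusted p = 0.00076) was lost at adjusted p = 0.0743 with an estimated correlation, and the mean per embryo was lower by -0.66 in NT embryos (permutation adjusted p = 7.7e-05, 15 of 15). LSS, which closes the sterol ring system, fell by 1.25 ± 0.22 (adjusted p = 4.04e-05, 15 of 15), the farnesyl diphosphate synthase FDPS by 1.12 ± 0.24 (adjusted p = 0.000516, 14 of 15) and the ATP citrate lyase ACLY by 0.47 ± 0.12. ACLY lost its call as deposited and with 1 probe per gene.

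Of 26 chromatin modifiers, 6 rose and 2 fell (camera adjusted p = 0.157), against 13 and 0 as deposited, and the mean per embryo was higher by 0.18 in NT embryos (permutation adjusted p = 0.00034, 15 of 15). The remodeller SMARCA2 (0.94 ± 0.14), the de novo methyltransferase DNMT3A (1.02 ± 0.22) and the deacetylase HDAC1 (0.40 ± 0.09) rose, and DNMT3A lost its call with the sample in Cy3 alone. Of 27 proteasome genes, 9 rose and 2 fell (adjusted p = 0.175), against 14 and 0 as deposited, among them PSMC2 (0.82 ± 0.13) and PSMA6 (0.73 ± 0.13), and the mean per embryo was higher by 0.17 (permutation adjusted p = 0.00042, 14 of 15). PSME3IP1 (1.39 ± 0.24), caught by the symbol pattern of this list, encodes a partner of a proteasome activator and no subunit. Of 31 trophectoderm genes, 3 rose and 7 fell (adjusted p = 0.157), with a median of -0.18 that turned to 0.20 as deposited, where 9 rose and 3 fell. TKDP4 (-1.08 ± 0.18), the desmosomal cadherin DSC2 (-1.24 ± 0.29) and the keratin KRT19 (-0.60 ± 0.15) fell, and the sodium pump subunit ATP1B3 rose (0.70 ± 0.12). KRT19 lost its call as deposited and with the sample in Cy5 alone, and the mean of this list per embryo was lower by -0.23 (permutation adjusted p = 0.0041, 14 of 15).

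Of 32 heat shock genes, 8 rose and 5 fell (adjusted p = 0.813), against 14 and 2 as deposited. HSP90AA1 (1.29 ± 0.17) and HSPE1 (0.94 ± 0.14) rose, and DNAJB1 (-0.97 ± 0.14) and HSF1 (-0.73 ± 0.11) fell, of which HSF1 lost its call as deposited. Of 28 antioxidant genes, 8 rose and 6 fell (adjusted p = 0.917), against 12 and 2 as deposited, with the mitochondrial proteins TXN2 at 0.98 ± 0.16 and PRDX3 at 0.90 ± 0.16, the thioredoxin reductase TXNRD1 at -1.12 ± 0.14 and GPX4 at -0.69 ± 0.11, of which GPX4 lost its call as deposited. Of 34 translation factors, 9 rose and 6 fell (adjusted p = 0.461), against 17 and 0 as deposited, among them EIF4A1, EIF4A2 (1.29 ± 0.22) and EIF3H (0.88 ± 0.10). The mean of this list per embryo was higher by 0.096 in NT embryos (permutation adjusted p = 0.045, 13 of 15). Of 45 ribosomal protein genes, 9 rose and 6 fell (adjusted p = 0.813), against 22 and 0 as deposited. The mean of that list per embryo differed by 0.018 (permutation adjusted p = 0.81, 9 of 15 NT embryos above the IVF mean). Among 4 measured pluripotency genes STAT3 (1.11 ± 0.20) and KLF4 (0.69 ± 0.18) rose and SALL4 (-0.58 ± 0.10) fell, the last of which lost its call as deposited. With arrays as deposited the median probe lay 0.37 higher in NT than in IVF embryos, and 2760 probes differed, 2675 higher and 85 lower, against 959 and 876 after centring. Of the 1835 probes 1044, and of 80 named genes past the threshold 61, kept their call as deposited, and the NT embryos labelled 3_ alone gave 1164.

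IVF embryos, set against AI embryos as fertilised embryos from culture, had lower transcripts of oxidative phosphorylation and histones. Ribosomal protein transcripts were lower as well, a list call lost at adjusted p = 0.0854 with an estimated correlation. TOMM7, a subunit of the mitochondrial import channel, fell by 1.61 ± 0.13 (15 IVF against 14 AI embryos, adjusted p = 9.37e-13) and lay below the AI mean in 15 of 15 IVF embryos. ZCCHC17 fell by 2.02 ± 0.19 (adjusted p = 3.6e-11, 15 of 15), and OCIAD2 rose by 2.18 ± 0.43 (adjusted p = 0.000115, 15 of 15). In all, 2113 probes differed, of which 1059 were higher and 1054 lower in IVF embryos, and 287 differed by at least 2-fold. At the level of genes 1299 differed, 611 higher and 688 lower.

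The other large rises were in FILIP1L (1.98 ± 0.31), HMOX1 (1.89 ± 0.33), the Wnt receptor FZD4 (3.37-fold), the small heat shock protein HSPB8 (1.68 ± 0.27), PLAU (1.65 ± 0.29), LOC532875 (1.62 ± 0.28), KCNK1 (1.57 ± 0.28), the sphingosine phosphate lyase SGPL1 (1.56 ± 0.22) and TSPAN12 (1.56 ± 0.37). The other large falls were in MPHOSPH8 (-1.96 ± 0.34), the immediate early gene EGR1 (-1.87 ± 0.34), the complement inhibitor CD59 (-1.82 ± 0.21), SH3BGRL (-1.73 ± 0.30), the pre-mRNA binding protein HNRNPC (3.31-fold), LARP7 (-1.67 ± 0.22), GAR1 (-1.66 ± 0.21) and PABPN1 (-1.64 ± 0.18). Adjusted p of these 17 genes lay between 2.35e-09 and 0.00122, and each lay on its side of the AI mean in 14 or 15 IVF embryos. All 20 of the largest changes kept their call as deposited and with either dye orientation alone.

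Of 53 genes of oxidative phosphorylation, 37 fell and 0 rose in IVF against AI embryos (37 fell and 1 rose when adjusted over the list alone), with a median of -0.51. As deposited 24 fell and 0 rose. Camera called the list (adjusted p = 7.96e-14), and the call held at adjusted p = 0.00269 with an estimated correlation. The mean per embryo was lower by -0.49 in IVF embryos (permutation adjusted p = 7.7e-05, 15 of 15 below the AI mean). COX7A2 fell by 1.33 ± 0.11 (adjusted p = 9.37e-13, 15 of 15), NDUFA2 by 1.06 ± 0.11, NDUFB9 by 1.10 ± 0.14 and UQCRQ by 1.06 ± 0.14. Of 45 ribosomal protein genes, 29 fell and 1 rose (31 and 1 when adjusted over the list alone), with a median of -0.36, against 16 and 1 and a median of -0.33 as deposited. The call (adjusted p = 7.99e-13) was lost at adjusted p = 0.0854 with an estimated correlation, and the mean per embryo was lower by -0.43 in IVF embryos (permutation adjusted p = 7.7e-05, 15 of 15). RPL35A fell by 1.32 ± 0.14 (adjusted p = 7.09e-10, 15 of 15), RPL23 by 0.87 ± 0.12, RPS3 by 0.89 ± 0.12 and RPL37 by 0.90 ± 0.13. Of the 10 genes in the histone list, 5 fell and 0 rose (7 fell when adjusted over the list alone; median -0.49, adjusted p = 0.00132, and adjusted p = 0.011 with an estimated correlation). H2AZ1 fell by 1.04 ± 0.09 (adjusted p = 2.19e-11, 15 of 15), H3-3A by 0.78 ± 0.15 and H2AZ2 by 0.74 ± 0.11, and without H19 5 of 9 fell (unadjusted p = 2.99e-05). As deposited 3 histone genes fell and 0 rose. The mean of the histone list per embryo was lower by -0.49 (permutation adjusted p = 7.7e-05, 15 of 15). IVF embryos entered both this comparison and that with NT embryos. Noise in IVF embryos alone thus links the falls here with the rises there, which are not separate findings.

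**Figure D2:**
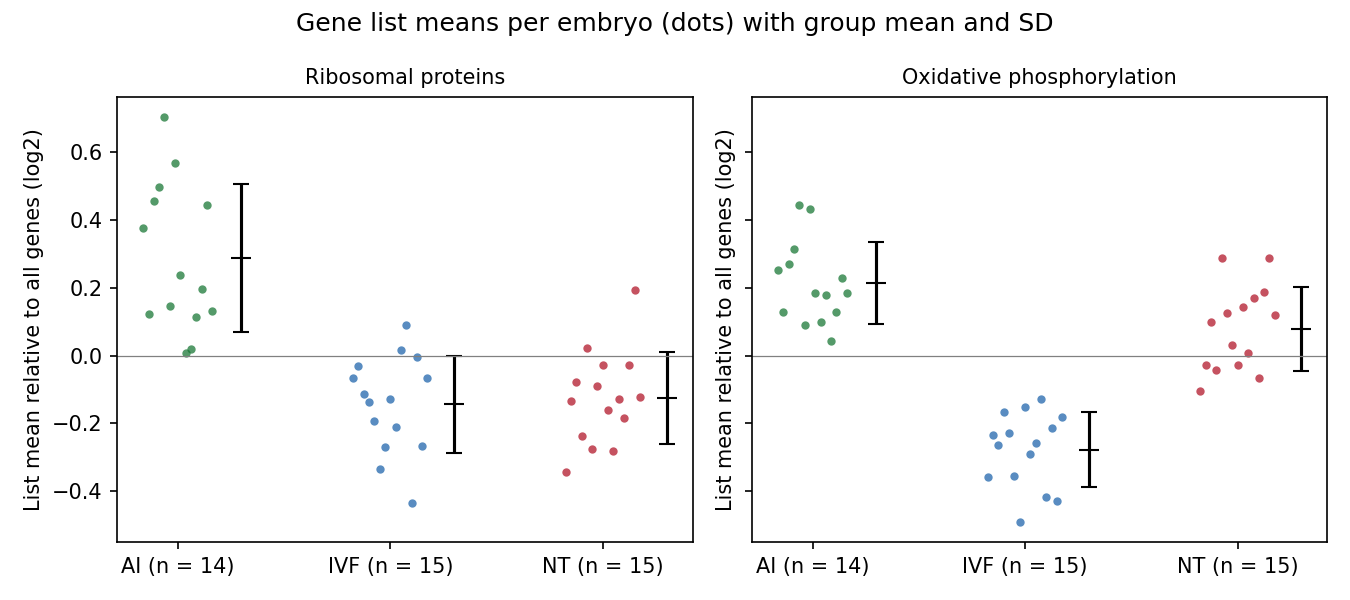
List mean (log2) of 45 ribosomal protein genes (left) and 53 genes of oxidative phosphorylation (right) in each embryo (y axis). Each gene was first set relative to its mean over all embryos, and the mean of all genes of that embryo was then subtracted. Values are thus deviations from the average embryo and not levels against other genes. Dots are embryos and bars the group mean and SD. Mean ± SD was 0.29 ± 0.22 in AI, -0.14 ± 0.14 in IVF and -0.13 ± 0.14 in NT embryos for ribosomal proteins, and 0.21 ± 0.12, -0.28 ± 0.11 and 0.079 ± 0.12 for oxidative phosphorylation.

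Of 27 proteasome genes, 3 rose and 11 fell in IVF against AI embryos (camera adjusted p = 0.346), against 3 and 6 as deposited, with PSMC2 at -0.81 ± 0.13, PSMA6 at -0.80 ± 0.13 and the activator PSME4 at 0.86 ± 0.14, and the mean per embryo was lower by -0.15 (permutation adjusted p = 0.0026, 13 of 15). Of 26 chromatin modifiers, 2 rose and 5 fell (adjusted p = 0.45), the same as deposited. DNMT3A (-1.56 ± 0.23), HDAC1 (-0.45 ± 0.09) and SMARCA2 (-0.79 ± 0.15) fell, CHD4 rose (0.85 ± 0.12), and the mean per embryo was lower by -0.13 (permutation adjusted p = 0.022, 12 of 15). Of 28 antioxidant genes, 6 rose and 9 fell (adjusted p = 0.82), against 5 and 3 as deposited. TXNRD1 (1.28 ± 0.15) and HMOX1 rose, and PRDX3 (-1.03 ± 0.16) and TXN2 (-0.96 ± 0.17) fell. Of 32 heat shock genes, 7 rose and 8 fell (adjusted p = 0.835), against 6 and 4 as deposited, with HSPB8 and DNAJB1 (0.64 ± 0.15) rising and HSP90AA1 (-1.54 ± 0.17) and HSPE1 (-0.97 ± 0.14) falling. Of 34 translation factors, 5 rose and 9 fell (adjusted p = 0.789), against 4 and 6 as deposited, among them EIF4A1 (-1.51 ± 0.17), EIF3H (-0.76 ± 0.10) and EIF5 (0.97 ± 0.20).

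Of 10 cholesterol and lipid synthesis genes, 3 rose and 1 fell in IVF embryos (adjusted p = 0.268), against 2 and 1 as deposited, with LSS at 1.07 ± 0.23 and EBP at -0.86 ± 0.20, and the mean per embryo was 0.30 higher (permutation adjusted p = 0.11, 13 of 15). This list varied more among AI embryos (SD 0.52) than among IVF embryos (SD 0.25). The 3 AI embryos labelled H lay at -0.22, -0.93 and -0.53 against an AI mean of 0.028, and the list member MSMO1 was lower by -2.78 ± 0.45 in them than in the other AI embryos (limma adjusted p = 0.000775), so that they bear on the list differences from AI embryos. Of 16 glycolysis genes, 3 rose and 4 fell (adjusted p = 0.789), against 1 and 2 as deposited, with LDHA at 0.93 ± 0.19 and TPI1 at -0.80 ± 0.12. Of 14 imprinted genes, PLAGL1 rose (0.61 ± 0.21) and CD81 fell (-0.69 ± 0.21), and both lost their call as deposited and with the sample in Cy3 alone (list adjusted p = 0.426). The mean of the imprinted list per embryo was 0.16 higher (permutation adjusted p = 0.012, 14 of 15). With arrays as deposited 1140 probes differed, 576 higher and 564 lower, of which 1136 were among the 2113, and 76 of 83 named genes past the threshold kept their call.

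NT and IVF embryos shared changes against AI embryos. Of the probes called in both comparisons, 124 were higher in both, 178 lower in both and 23 opposite, against 35.1 and 43.9 for independent comparisons. CASP6 was 2.26-fold lower in NT and in IVF embryos, and OCIAD2 and KCNK1 were higher in both. Because AI embryos entered both comparisons, noise alone links the differences. Their covariance was 0.0714 against 0.0231 in simulated data without changes, and 0.0434 when the AI embryos were divided so that the comparisons shared none. Their correlation was 0.465, below the 0.523 in those simulated data, and 0.238 with AI embryos divided.

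**Figure D3:**
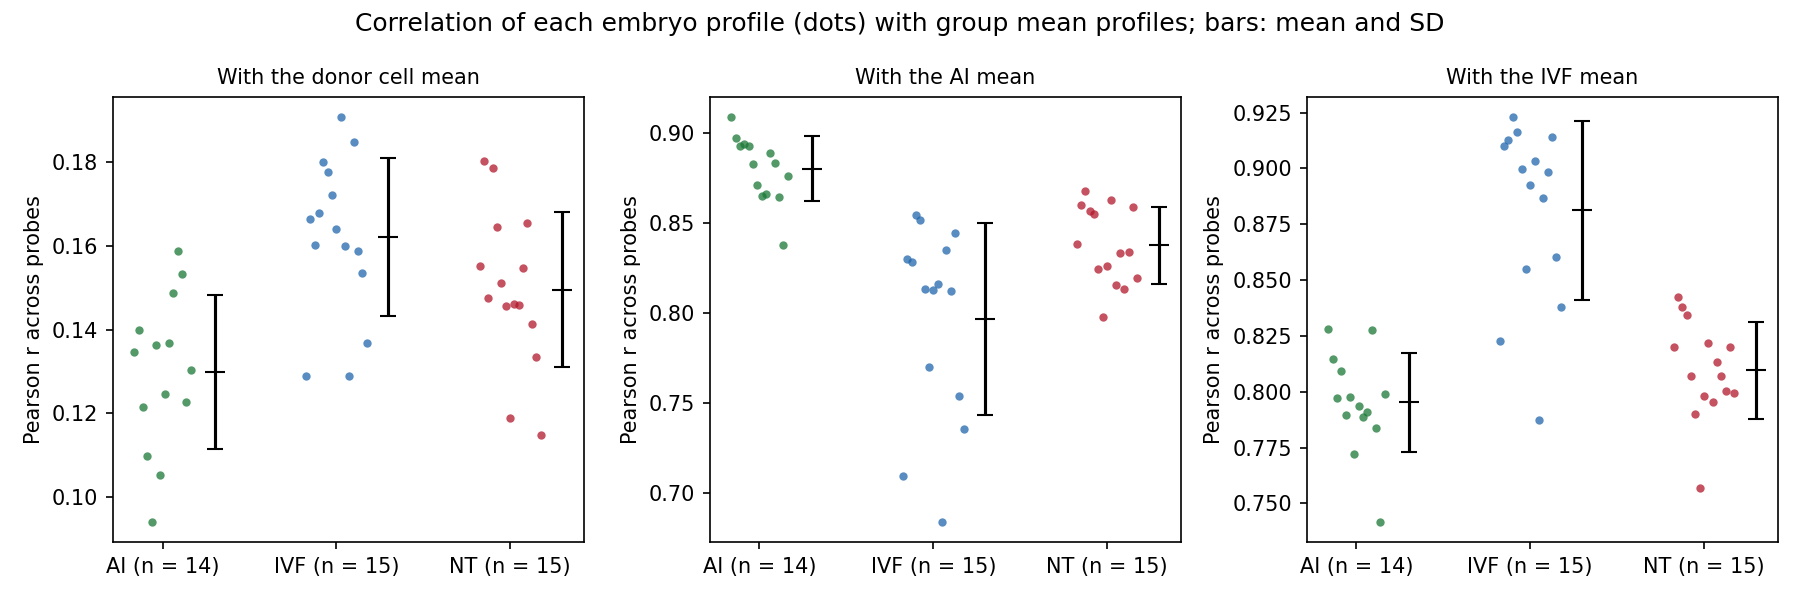
Pearson r across probes of each embryo (dots) with the mean of the donor cells (left), of AI embryos (middle) and of IVF embryos (right), with bars for the group mean and SD; the mean of its own kind contains the embryo itself. Mean r with the donor cells was 0.130 in AI, 0.162 in IVF and 0.150 in NT embryos.

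The 15 NT embryos all correlated more with the AI mean (r 0.838 ± 0.022, SD) than with the IVF mean (0.810 ± 0.022, SD). Mean profiles correlated at 0.943 between AI and NT, at 0.912 between IVF and NT and at 0.902 between AI and IVF embryos. These are correlations across probes, which are not independent replicates. Embryos correlated with the other embryos of their kind at 0.858 ± 0.021 (SD, n = 14) in AI, 0.862 ± 0.047 (SD, n = 15) in IVF and 0.868 ± 0.021 (SD, n = 15) in NT embryos. The differences did not pass (permutation adjusted p = 0.72 for NT minus AI at 0.0095, 0.81 for NT minus IVF at 0.0062 and 0.81 for IVF minus AI at 0.0033).

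All 3 kinds of embryo were far from the donor cells. The direction of the ratio, on which every direction given here depends, was checked only by the fibroblast and trophectoderm lists in this comparison, so that the direction of these 2 lists against donor cells is no finding of its own. NT embryos had lower FMOD (-6.78), CTSK (-6.75), CAV1 (-6.64), TCIM (-6.62), DCN (-6.45) and COL3A1 (-6.13 ± 0.24) and higher OCLN (5.73), KRT8 (5.42 ± 0.29), PTGS2 (5.38), ESRP1 (5.29) and AQP3 (5.07) than donor cells. FMOD, DCN and COL3A1 encode proteins of the collagen matrix and CTSK a collagen-degrading protease, and OCLN, KRT8, ESRP1 and AQP3 are epithelial genes. COL3A1 had an adjusted p of 8.8e-26 and KRT8 of 1.66e-20 (15 NT embryos against 2 donor cell samples, 15 of 15 on that side of the donor mean). The spread was estimated over all groups and thus mostly from embryos. The p values and counts against donor cells therefore assume that donor cell samples vary like embryos. Of 7992 probes, 2506 differed in NT (1336 higher and 1170 lower in embryos), 2636 in AI (1386 and 1250) and 2489 in IVF embryos (1283 and 1206). Among them 1839 probes differed in all 3 comparisons with the same sign, 942 higher and 897 lower in embryos. The comparisons share the donor cells, and with 2 samples these could not be divided, so that part of the overlap may rest on them. The covariance of the differences was 1.43 for AI and NT and 1.37 for AI and IVF embryos, against 0.150 in simulated data without changes. The correlations were 0.961 and 0.933, against 0.872 in those simulated data.

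The largest differences of AI embryos from donor cells were OCLN (6.08) and TCIM (-7.17), and those of IVF embryos OCLN (6.04) and TCIM (-7.14). HKDC1, a hexokinase-like gene, was higher by 5.69 in both, and EGR1 was 65.6-fold lower in IVF embryos. Of 30 fibroblast and matrix genes, 15 were lower and 1 higher in NT, 16 and 1 in AI and 19 and 3 in IVF embryos. VIM was lower by -4.48 ± 0.18 and COL1A2 by -5.26 ± 0.23 in NT embryos. Of 31 trophectoderm genes, 15 were higher and 2 lower in NT, 16 and 2 in AI and 19 and 2 in IVF embryos, with the tight junction gene CLDN6 at 3.80 ± 0.21 in NT and KRT18 at 5.13 ± 0.33 in IVF embryos. Of 20 cell cycle and DNA replication genes, 14, 14 and 15 were higher and 1 was lower in each (adjusted p = 5.13e-06, 4.82e-06 and 3.97e-07), among them CDC20 (4.10 ± 0.31) and MCM4 (3.46 ± 0.28) in NT embryos. As deposited 13, 11 and 10 were higher, and the cell cycle list kept its call with an estimated correlation in all 3 kinds of embryo (adjusted p = 0.00307, 0.00361 and 0.00102).

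Of 53 genes of oxidative phosphorylation, 29 were higher and 1 lower in NT embryos than in donor cells (adjusted p = 5.47e-06, and adjusted p = 0.0512 with an estimated correlation). The counts were 34 and 0 in AI embryos (adjusted p = 3.49e-07, and 0.0255 with an estimated correlation) and 14 and 2 in IVF embryos (adjusted p = 0.0242, and 0.352 with an estimated correlation). As deposited 29, 18 and 5 were higher and 0, 0 and 2 lower in NT, AI and IVF embryos, and the list call in IVF embryos was lost. COX7A2 was higher by 2.72 ± 0.22 in NT, 3.01 ± 0.22 in AI and 1.67 ± 0.22 in IVF embryos. Of 45 ribosomal protein genes, 20 were lower and 2 higher in NT (adjusted p = 3.9e-05, and 0.279 with an estimated correlation) and 22 and 2 in IVF embryos (adjusted p = 2.1e-05, and 0.32 with an estimated correlation). In AI embryos 9 were lower and 4 higher (adjusted p = 0.301). As deposited 5, 19 and 8 were lower and 2, 1 and 2 higher in NT, IVF and AI embryos. RPS9 was lower by -4.82 ± 0.31 in NT embryos, and RPL7L1, a paralogue of RPL7 caught by the symbol pattern of this list, was higher by 1.79 ± 0.22.

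Of 32 heat shock genes, 12 were higher and 1 lower in NT, 14 and 1 in AI and 12 and 0 in IVF embryos (adjusted p = 0.00618, 0.00511 and 0.00458, and adjusted p = 0.176, 0.15 and 0.168 with an estimated correlation), among them HSF1 (2.23 ± 0.23) and HSPE1 (2.38 ± 0.29) in NT embryos. Of 16 glycolysis genes, 9 were higher in each kind of embryo and 2, 2 and 1 lower (adjusted p = 0.0255, 0.00566 and 0.00603, and adjusted p = 0.176, 0.0882 and 0.109 with an estimated correlation), with the glucose transporters SLC2A1 at 3.64 ± 0.35 and SLC2A3 at 3.04 ± 0.29 in NT embryos. Of 14 imprinted genes, 6 were lower and 0 higher in NT (adjusted p = 0.032, and 0.0512 with an estimated correlation) and in AI embryos (adjusted p = 0.0276, and 0.0394 with an estimated correlation), and 3 were lower and 1 higher in IVF embryos (adjusted p = 0.0681). As deposited 12, 6 and 6 heat shock genes and 8, 6 and 5 glycolysis genes were higher, and 2, 5 and 3 imprinted genes lower, in NT, AI and IVF embryos, and the call of the glycolysis list in NT embryos was lost. PLAGL1 was lower by -4.64 ± 0.42 and IGF2R by -0.85 ± 0.25 in NT embryos, a call that IGF2R lost as deposited and with the sample in Cy3 alone, and IGF2R did not pass in IVF embryos (-0.57 ± 0.25, adjusted p = 0.0673, 14 of 15). HDAC1 was higher by 2.59 ± 0.18 in NT embryos, and DNMT3A by 2.60 ± 0.46 in AI embryos, a call lost with the sample in Cy3 alone, and DNMT3A did not pass in IVF embryos (1.04 ± 0.46, adjusted p = 0.0732).

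Each donor cell sample weighed heavily on these counts. Without donor cell sample 8 they fell to 1618 in NT, 1691 in AI and 1536 in IVF embryos, and without sample 9 to 1611, 1697 and 1598, where the remaining sample is assumed to vary like the other groups. With arrays as deposited the median probe shifted by 0.19, -0.25 and -0.17, and 1255 probes were higher and 682 lower in NT, 758 and 1194 in AI and 668 and 1092 in IVF embryos.

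Whether NT embryos resembled the donor cells more than fertilised embryos do was asked with a value per embryo. Mean r with the donor cells was 0.130 ± 0.018 (SD, n = 14) in AI, 0.162 ± 0.019 (SD, n = 15) in IVF and 0.150 ± 0.019 (SD, n = 15) in NT embryos. NT embryos exceeded AI embryos by 0.0197 (permutation p = 0.0077, adjusted p = 0.012) and IVF embryos exceeded AI embryos by 0.0322 (permutation p = 6e-05, adjusted p = 0.00018). NT and IVF embryos differed by -0.0125, which did not pass (permutation adjusted p = 0.078), whereas with Spearman correlation the difference of -0.0203 passed (permutation adjusted p = 0.032). The orders against AI embryos held in neither dye orientation alone. NT minus IVF turned with the sample in Cy5 alone, to 0.0247 (permutation adjusted p = 0.31), but not with the sample in Cy3 alone. With the sample in Cy5 alone the differences were -0.0228 for NT minus AI (permutation adjusted p = 0.31) and -0.0475 for IVF minus AI (permutation adjusted p = 0.17), and in Cy3 alone they were -0.0477 and -0.0411 (permutation adjusted p = 0.21 for both).

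Across the 2636 probes that separated AI embryos from donor cells, the NT minus IVF difference had a slope of -0.0427 on the donor cell minus AI difference (permutation p = 1e-04, the smallest that the permutations can give). Here 0 means that NT embryos lay no nearer to the donor cells than IVF embryos along this difference. A slope of 1 means a difference as large as that of donor cells from AI embryos. For the other pairs, the slope of NT minus AI on donor cell minus IVF was 0.0214 (permutation p = 0.0082, 2489 probes), and that of IVF minus AI on donor cell minus NT was 0.0654 (permutation p = 1e-04, 2506 probes). AI and IVF embryos never held a donor nucleus, so that the slope measures nearness to the donor cells and not what a donor nucleus left behind. The slopes were not computed in single dye orientations. Of the probes called in both comparisons, NT embryos lay on the donor cell side of AI embryos in 158 of 268 (59.0%) and on the donor cell side of IVF embryos in 269 of 810 (33.2%), and IVF embryos lay on the donor cell side of AI embryos in 622 of 897 (69.3%). The side of the donor cells was taken in each case from a comparison that shared no embryos with the first.

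Of the 31 list calls made by camera over the 6 comparisons, 16 held with an estimated correlation. These were ribosomal proteins in NT against AI, oxidative phosphorylation and histones in NT against IVF and in IVF against AI, the fibroblast, trophectoderm and cell cycle lists against donor cells in each kind of embryo, and oxidative phosphorylation and imprinted genes in AI embryos against donor cells. In all 31 the median, mean and test had the same sign. As deposited 28 of the 31 calls and with quantile normalisation 30 held. In lists not called they differed for antioxidants, histones, cell cycle and interferon response in NT against AI, for heat shock and ribosomal proteins in NT against IVF, and for heat shock, antioxidants, cell cycle and apoptosis in IVF against AI. Against donor cells they differed for primitive endoderm in each kind of embryo, and for interferon response in NT, cholesterol synthesis in AI and translation factors in IVF embryos.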

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

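Arrays as deposited and IVF embryo 11 left out were chosen after seeing the data. As deposited, 3194 probes differed in NT against AI, 2760 in NT against IVF and 1140 in IVF against AI embryos. In NT against AI these named genes turned, without passing, to 0.028 (PAG8), 0.0171 (CCT3), 0.0453 (GPX4), 0.0294 (EIF3CL) and 0.0386 (PSMA7), and in NT against IVF to 0.0179 (CDKN1A), 0.0109 (PDCD6) and 0.0286 (LAPTM5). Uncentred arrays add the shift of the median probe to every difference. Of 475 calls of named genes 404 stayed past the threshold as deposited, 470 with quantile normalisation, 468 with scaling to a common median absolute deviation, 430 with the sample in Cy5 alone, 423 in Cy3 alone and 460 with 1 probe per gene. LAPTM5 turned to 0.0235 with Cy5 alone in NT against IVF, and COL12A1 to 0.0519 with 1 probe per gene in IVF against AI, and the cause was not tested.

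NT against AI gave 1016 probes with the sample in Cy5 alone and 319 in Cy3 alone, for which the cause was not tested. Stricter thresholds gave fewer probes by construction. At an adjusted p of 0.01 they were 249 in NT against AI, 1120 in NT against IVF and 1265 in IVF against AI, and with at least 2-fold change 68, 206 and 287. Per gene symbol, with fewer features tested, 355, 1066 and 1299 differed, and against donor cells 1558 in NT, 1627 in AI and 1508 in IVF embryos. With fewer NT embryos, those labelled 2_ gave 321 and those labelled 3_ 294 against AI, and those labelled 3_ gave 1164 against IVF. Leaving out each sample gave 490 to 621 in NT against AI, 1706 to 1861 in NT against IVF, 1977 to 2115 in IVF against AI, 1611 to 2504 in NT, 1691 to 2630 in AI and 1536 to 2523 in IVF embryos against donor cells, where the lowest counts were those without 1 of the 2 donor cell samples. Under the other alternatives fixed before the data were examined each count stayed within 1.5 times.

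The numbers of AI and IVF embryos do not pair them: deviations of the same number correlated from -0.0587 to 0.0393. With the shared numbers as a block IVF against AI gave 629 probes, and the same embryos without the block gave 1006.

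The difference in r with donor cells turned with Cy5 alone, to -0.0228 for NT minus AI, 0.0247 for NT minus IVF and -0.0475 for IVF minus AI, and with Cy3 alone to -0.0477 for NT minus AI and -0.0411 for IVF minus AI. With Spearman correlation NT minus IVF passed at -0.0203. The difference in r with the own kind, which never passed, turned for IVF minus AI to -0.00136 with complete probes and -0.0127 with Cy5 alone, for NT minus AI to -0.00336 and NT minus IVF to -0.0111 with Cy3 alone, and for NT minus IVF to -0.00175 without IVF embryo 11. The cause was not tested for any of these. With AI and IVF exchanged, which makes it another comparison, the slope on the donor cell difference was 0.0214.

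Of 31 list calls 16 held with an estimated correlation, which left 1 in NT against AI and 3 each in NT and IVF embryos against donor cells. As deposited 28 of the 31 held, and the calls lost were oxidative phosphorylation in NT against AI and in IVF embryos against donor cells and glycolysis in NT embryos against donor cells. With quantile normalisation 30 held, and trophectoderm in NT against AI was lost. Fry, which does not compare a list with other genes, called 9 in NT against IVF, 9 in IVF against AI, and 11 each in AI and IVF embryos against donor cells. Signal over background could not be examined, since no intensities were held.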

Other observations

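The tests of a dye effect as the whole cause, of list means per embryo, of NT embryos against median profiles and dye bias, and of the AI embryos labelled H and the NT embryos labelled 2_ and 3_, were chosen only after the results were seen. HSD3B1, an enzyme of progesterone synthesis, was higher in IVF than in AI embryos (1.01 ± 0.32, adjusted p = 0.0136, 13 of 15) and lower in NT than in IVF embryos (-1.34 ± 0.31, adjusted p = 0.00114, 15 of 15), and lost both calls with the sample in Cy5 alone and the first also in Cy3 alone. The other cumulus cell genes measured, TNFAIP6 and CYP19A1, did not pass in any comparison of embryos. MUC1, from the list of endometrium and oviduct with 3 members, was higher in IVF than in AI embryos (0.68 ± 0.18, adjusted p = 0.00395, 15 of 15), a call lost with the sample in Cy3 alone, and SPP1 and MSX1 did not pass. STAT3 was lower (-1.41 ± 0.20, adjusted p = 8.12e-07, 15 of 15) and SALL4 higher (0.50 ± 0.10, adjusted p = 0.000247, 14 of 15) in IVF than in AI embryos, and none of 4 pluripotency genes passed in NT against AI. ZP3, the only oocyte gene measured, did not pass between embryos, and of mitochondrially encoded genes 0 were measured.

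Of 9 primitive endoderm genes, LAMB1 rose (1.10 ± 0.17) and DAB2 (-1.43 ± 0.26) and TF (-0.48 ± 0.12) fell in IVF against AI embryos, and in NT against AI LAMB1 rose (0.66 ± 0.17) and COL4A1 fell (-0.63 ± 0.14, lost as deposited, where 3 rose and 0 fell). Of 30 fibroblast and matrix genes, 3 rose and 1 fell in NT against AI, 7 and 5 in NT against IVF and 5 and 5 in IVF against AI embryos (camera adjusted p = 0.925, 0.813 and 0.82), against 15 and 0, 13 and 1 and 3 and 2 as deposited, with CCN2 at 0.76 ± 0.14 and FN1 at -0.80 ± 0.15 in IVF against AI. Of 20 cell cycle genes, 4 rose in IVF against AI, among them BUB3 (0.50 ± 0.10) and the inhibitor CDKN1A (0.59 ± 0.13), and 3 fell in NT against IVF, CDK4 (-0.53 ± 0.14), CDKN1A (-0.36 ± 0.13) and CCNE1 (-0.57 ± 0.20), each of which lost its call as deposited, where 5 other members rose. The list means per embryo were lower in NT than in IVF embryos for cell cycle (-0.12, permutation adjusted p = 0.04, 11 of 15, camera adjusted p = 0.431) and for 14 imprinted genes (-0.12, permutation adjusted p = 0.044, 12 of 15, camera adjusted p = 0.525), of which DLK1 and CD81 fell and MEST rose. As deposited 4 imprinted genes rose and 0 fell, MEST lost its call with the sample in Cy5 alone and DLK1 in Cy3 alone. Of 9 apoptosis genes, 3 rose and 3 fell in IVF against AI, against 1 and 3 as deposited, with AIFM1 1.99-fold lower and CASP2 at 0.84 ± 0.19. Of 9 interferon response genes, IRF9 fell in NT against IVF (-0.51 ± 0.13, lost as deposited), and by limma 0 passed one by one between NT and AI or IVF and AI embryos. The mean of this list per embryo was higher in IVF than in AI (0.17, permutation adjusted p = 0.026, 12 of 15, camera adjusted p = 0.45) and lower in NT than in IVF embryos (-0.16, permutation adjusted p = 0.037, 13 of 15, camera adjusted p = 0.395). Of 10 blood and immune cell genes, CD3D rose in IVF against AI (0.61 ± 0.20) and S100A12 (-0.49 ± 0.17) and LAPTM5 (-0.35 ± 0.13) fell in NT against IVF. CD3D and S100A12 lost their call in either dye orientation alone and LAPTM5 with the sample in Cy5 alone, and S100A12 and LAPTM5 also as deposited. LAPTM5 lost it also with quantile normalisation and with scaling to a common median absolute deviation.

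Transcripts of ribosomal proteins and oxidative phosphorylation were lower in IVF than in AI embryos. The camera call of the ribosomal list was lost at adjusted p = 0.0854 with an estimated correlation. Compression towards the reference by an amount set by the ratio alone is argued against for either list. The list medians were -0.36 and -0.51, whereas 10000 random lists matched on mean log ratio centred on 0.032 and 0.016, with the real lists at percentile 0. Compression that depends on signal intensity stays open, since no intensities were held. A dye effect is argued against for oxidative phosphorylation, where the smaller median fall of the dye orientations over the larger was 0.698, and for ribosomal proteins it was 0.457, short of the bound set beforehand (-0.53 with the sample in Cy5, 32 lower and 1 higher, and -0.24 in Cy3, 14 lower and 0 higher). That bound asked too much, since a dye effect changes sign between the orientations and cancels in their mean, and as the whole cause it is argued against for both lists, since the list means per embryo fell in each, with upper 95% bounds of at most -0.153 for ribosomal proteins and -0.34 for oxidative phosphorylation. Unequal amplification of short and long transcripts stays open, since the percentiles of 0.01 and 0 among lists matched on genomic span say little about transcript length. A difference between embryos from culture and from insemination was not tested apart from hybridisation batch and may account for it as well. A cause acting alike on IVF and NT embryos is argued against as the whole cause for oxidative phosphorylation. There the list mean per embryo differed from AI by -0.49 in IVF but by -0.13 in NT embryos, and 15 of 15 NT embryos lay above the IVF mean. For ribosomal proteins the differences were -0.43 and -0.41, so that such a cause stays open. Whether culture acted alike on both was not tested.

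NT embryos lay nearer to AI than to IVF embryos. A few deviating IVF embryos are argued against, since 15 of 15 NT embryos also correlated more with the AI median profile. The dye bias of the arrays gave no sign that hybridisations of NT and AI embryos were technically more alike, since it was nearer to AI in 6 of 15 NT embryos. A share so near an even split would also arise if dye bias told nothing of shared hybridisation conditions. Batches that leave no dye bias, and a likeness in biology, which was not tested, stay open. Each could account for NT embryos lying nearer to AI embryos.

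Of 100 splits of the embryos, the real one included, 1 gave as many probes in each comparison of embryos, so that chance is argued against. With 100 splits no share below 1 in 100 can be shown, and the splits do not part kind of embryo from batch. The real counts were 598, 1835 and 2113, against at most 1, 1 and 182 in other splits. For the number of lists called by camera chance could not be excluded. The real split gave 3 lists in each comparison, and 12 of 100 splits gave as many in NT against AI (highest other 5), 19 in NT against IVF (highest other 6) and 17 in IVF against AI (highest other 5).

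The 3 AI embryos labelled H differed from the 11 others in 37 probes by limma, with TXNIP (-2.86 ± 0.43) and MSMO1 (-2.78 ± 0.45) lower. Chance is argued against, since 1 of 100 splits, the real one, gave as many and the highest other gave 11. It is not excluded, since this grouping was tested only after the results were seen. NT embryos labelled 2_ and 3_ differed in 0 probes by limma, with 635 at an unadjusted p under 0.05, and a count of 0 is reached by all 100 splits whatever the data, so that the splits test nothing here (highest other 1). IVF embryo 11 deviated most from its kind (SD 0.826), and the deviations of its 2 arrays correlated at 0.449.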
